A study of Gallus gallus with 10 samples.

How the data were processed

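Otocysts, the epithelial vesicles that give rise to the inner ear, were taken from White Leghorn chicken embryos at embryonic day 2.5 and cleared of mesenchyme. From each of 5 embryos, numbered 76, 77, 79, 81 and 82, the right otocyst was cultured for 24 h in medium with 300 µM IWR-1, a tankyrase inhibitor that stabilises axin and so lowers canonical Wnt signalling. The left otocyst of each embryo was cultured in medium with the solvent DMSO. Each otocyst gave 1 library, so there were 10 libraries, 5 per group. IWR-1 always went to the right side, so that treatment and body side cannot be separated in any comparison. Per the labels' protocols, libraries were made with a low-input kit that amplifies cDNA by template switching, and the ligated adaptor carried a molecular identifier. Whether the identifiers were used in counting is not given in the sources used here, so reads are not taken to be independent molecules. The series text spells the compound and gives the embryonic day differently from the sample labels, and the sample labels were followed.

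The deposited tables have the layout of kallisto output, and the submitters' processing notes name bcl2fastq, kallisto and the build GRCg6a, with versions not given in the sources used here. Each deposited table gives an estimated count and a TPM value for 25756 sequences, which are 25747 Ensembl chicken transcripts and 9 added reporter or construct sequences. The deposited estimated counts are not normalised, and a read that fits several transcripts is divided among them. The deposited TPM values were scaled by the authors' software to transcript length and to a fixed sum per library. Effective lengths were identical in all libraries, so length offsets and length-scaled counts would equal the counts as used and were not run as separate alternatives. Total estimated counts lay between 24470010 and 28572053 per library.

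The files do not pair transcript IDs with gene names. The reference table of gene names (assembly GRCg7b) matched 0 of the 25747 IDs. The 33 gene lists fixed before the data were examined, the count of Wnt target genes, the tests of gene lists, the rule for named genes and the shares of mitochondrial and ribosomal transcripts all need names and were not run. The planned fallback was used, a test per transcript. A correction for GC content was not run, since transcript sequences were not used here.

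Estimated counts were rounded to whole numbers. In R 4.3.3 the planned test was the quasi-likelihood test of edgeR 4.0.16 with robust shrinkage, TMM normalisation and the default expression filter, which left 17504 transcripts. It was two-sided, without an embryo term, and transcripts were called at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are IWR-1 over DMSO, and the error of a log2 fold change is its size divided by the root of the F statistic. Alternatives fixed in advance were an embryo block, other normalisations, DESeq2 1.42.0, limma-voom (limma 3.58.1), TPM with pseudocounts of 1 and 0.1, other filters, stricter thresholds, and leaving out each library and each embryo. The embryo numbers pair the samples, since both otocysts of an embryo were taken. As a check, deviations from the group mean correlated at 0.152 to 0.195 between the otocysts of 1 embryo and at -0.142 to 0.106 between otocysts of different embryos, across transcripts, which are not independent replicates.

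After the planned results were seen, transcripts were also divided by whether their counts carried decimals. A transcript whose count was printed without decimals in all 10 libraries is called a whole-count transcript. Such counts show no divided read, but do not show that no read fitted another transcript, and an undetected transcript also passes. There were 10111 whole-count transcripts, holding 41.8% of the counts. The format prints large counts without decimals, so the 11 transcripts with at least 100000 counts in a library could pass regardless. The others are called split-count transcripts. Whole-count transcripts were tested alone with the embryo block. That fit was picked after the counts of calls from 17 fits, itself among them, had been seen, and 10 of the 17 gave 3 calls or fewer. Its count of calls is therefore a selected result and its adjusted p-values do not allow for that selection. With no gene names, 2 transcripts with the smallest p in each direction are named, a choice made after their values were seen.

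The tests were tested on simulated data, with counts drawn from the real means, library sizes and the dispersions per transcript of the embryo-block fit. There were 3 simulations of IWR-1 against DMSO with 200 changed transcripts each. Division of reads among transcripts was not simulated, so the shares below may not hold for split-count transcripts. The shares also depend on the number of changed transcripts, which was set. With the embryo block edgeR made 361 calls over the 3 simulations, against 0 on the real data. The simulated setting therefore differs from the real one, and the real recovery may be lower. Over 16861 transcripts, the planned test recovered 21.5% of those changed 1.5-fold, 41.6% of those changed 2-fold and 72% of those changed 4-fold, with 0.4% false calls. With the embryo block the recovered shares were 37.4%, 53.8% and 79.8%, with 7.8% false calls. On 6248 whole-count transcripts with the block they were 58.3%, 68.2% and 95.6%, with 7.3% false calls. DESeq2 on 17504 transcripts gave 7.7% false calls without the block and 35% with it. All of these but the planned test lay above the 5% set by the threshold. Library measures were compared with exact permutation tests over the 252 assignments of group labels.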

Results

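RNA was sequenced from 10 single chicken otocysts, 5 cultured with IWR-1 and 5 with DMSO. The question was which transcripts change with a drug meant to lower canonical Wnt signalling. Whether Wnt signalling fell in these otocysts was not checked, since the count of Wnt target genes needs gene names. Total estimated counts were 26024252 to 28572053 in the IWR-1 libraries and 24470010 to 27243498 in the DMSO libraries, a difference in means that a two-sided exact permutation test did not separate from chance (p = 0.135, adjusted p = 0.365 over 4 measures). The 20 most abundant transcripts held 9.04% ± 0.229 of counts with IWR-1 and 8.77% ± 0.337 with DMSO (SD, n = 5, exact permutation p = 0.182, adjusted p = 0.365). Both measures were higher with IWR-1 in 4 of 5 embryos. Within pairs the exact permutation p was 0.125 for the totals and 0.1875 for the top 20 (adjusted p = 0.375 for both). The smallest p that 5 pairs allow is 0.0625.

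Transcript ENSGALT00000040012.2 was lower with IWR-1 and had the smallest p in the planned test, which has no embryo term. It averaged 1.37 ± 0.578 CPM with IWR-1 and 38.3 ± 17.2 CPM with DMSO (SD, n = 5), which is 27.9-fold lower, and it was lower in 5 of 5 embryos. Its log2 fold change was -4.80 (SE 0.44), with an adjusted p of 0.00998 in edgeR's quasi-likelihood test without an embryo term. With the embryo block the log2 fold change was -4.71 (SE 0.37) and the adjusted p 0.0706, so the call was lost although the fold was nearly the same. Of the blocked fits chosen after the data were seen, it passed in limma-voom (adjusted p = 0.0114), in edgeR without robust shrinkage (0.0447) and in edgeR at mean counts of at least 100 and 500 (0.0274 and 0.00526). It did not pass in edgeR with a length correction (0.0718) or on split-count transcripts alone (0.0736). Of the alternatives fixed in advance, limma-voom without the block gave adjusted p-values of 0.182, or 0.104 with sample weights. DESeq2, also fixed in advance, called ENSGALT00000040012.2 without the block (adjusted p = 5.07e-30) and with it (9e-27). DESeq2 with the block made 35% false calls in simulated data. Limma on TPM, without the block, called it at pseudocounts of 1 and 0.1 (adjusted p = 0.00587 and 0.00318). The counts of ENSGALT00000040012.2 held reads divided with 1 other transcript, which was given at most 23.6 counts in any library. How many reads fit both transcripts is not known, so how much of its level is uncertain cannot be said. Which gene it belongs to is not stated here, because the files do not pair transcript IDs with names.

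ENSGALT00000040012.2 was the only transcript of 17504 that passed the planned test, and no transcript passed as higher with IWR-1. Without the IWR-1 library of embryo 76, 77 or 79 its edgeR adjusted p was 0.0876, 0.0588 or 0.0646, and without both otocysts of embryo 76, 77, 79 or 81 it was 0.127, 0.203, 0.176 or 0.0846. Without any other single library its edgeR adjusted p was 0.000565 to 0.0437, and without both otocysts of embryo 82 it was 0.00586. The log2 fold change without embryo 76, 77, 79 or 81 stayed between -5.01 and -4.59. At an unadjusted p under 0.05 there were 1148 transcripts, where 875 would be reached by chance. The embryo block gave 0 calls in edgeR, with 1765 transcripts at an unadjusted p under 0.05. Other tools gave different counts. DESeq2 called 134 transcripts, 39 higher and 95 lower, and with the block 614, of which 252 were higher and 362 lower. Limma-voom called 0 transcripts, and 8 with the block. In simulated data 35% of the calls of DESeq2 with the block were false, so its 614 calls are not read as a count of changed transcripts. The planned test recovered 41.6% of simulated 2-fold changes, with 200 changed transcripts per simulation, so that changes of this size could often be missed. If fewer transcripts changed in the real data, the recovered share may be smaller.

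ENSGALT00000060409.1, a whole-count transcript, had the second smallest p. It averaged 37.8 ± 6.82 CPM with IWR-1 and 74.3 ± 10.6 CPM with DMSO (SD, n = 5) and was lower in 5 of 5 embryos. The log2 fold change was -0.98 (SE 0.14) with an adjusted p of 0.116 in edgeR, or 0.059 with the embryo block over all transcripts, where it ranked ahead of ENSGALT00000040012.2. The transcripts with the smallest p in the other direction did not pass the planned test either. ENSGALT00000055528.1 averaged 263 ± 5.19 CPM with IWR-1 and 203 ± 16.3 CPM with DMSO (SD, n = 5; log2 fold change 0.37, SE 0.06, edgeR adjusted p = 0.127). ENSGALT00000019502.3 averaged 94.4 ± 3.93 CPM and 75.5 ± 3.37 CPM (SD, n = 5; log2 fold change 0.32, SE 0.05, edgeR adjusted p = 0.127). Both were higher with IWR-1 in 5 of 5 embryos. Each of these 2 passed in 3 of the 40 alternatives that tested it, and ENSGALT00000060409.1 in 9 of 40. In DESeq2 the adjusted p of ENSGALT00000060409.1 was 5.73e-08, or 2.42e-36 with the block. The DESeq2 adjusted p-values of the 2 higher transcripts were 1.03e-06 and 2.42e-07, or 2.48e-11 and 7.01e-07 with the block. In edgeR with the block at a mean count of at least 500 the adjusted p-values of these 2 were 0.0258 and 0.0451.

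**Figure D1:**
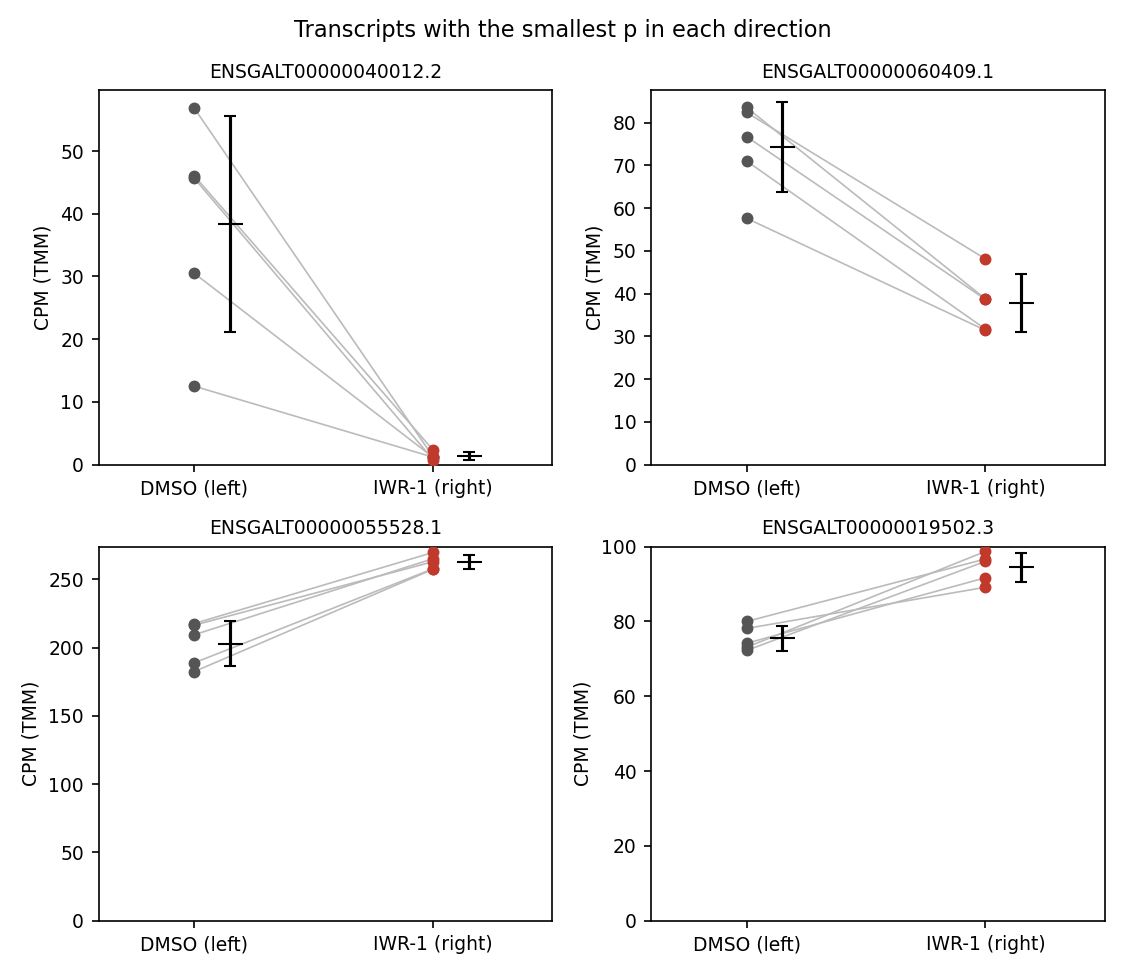
Level of the 4 named transcripts in CPM in each library (vertical axis, from 0) for DMSO and IWR-1 otocysts (horizontal axis), with grey lines joining the otocysts of 1 embryo and black marks giving the mean ± SD of 5. ENSGALT00000040012.2 lay between 0.821 and 2.35 CPM with IWR-1 and between 12.5 and 56.9 CPM with DMSO.

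Groups that did not overlap were counted without a model. In 109 transcripts all 5 IWR-1 libraries lay above all 5 DMSO libraries, and in 175 all lay below, where chance gives 0.4% of transcripts, or 69.5, in each direction if the 10 libraries are exchangeable. They are paired by embryo, and over the 15 other splits that part all 5 pairs the total of both directions had a median of 66 and a highest value of 191, against the observed 284. Of these 284, 14 were more than 2-fold lower and 3 more than 2-fold higher. The median log2 difference was -0.38 among the lower and 0.34 among the higher. All 5 embryos differed in the same direction for 944 transcripts higher and 1077 lower with IWR-1, where chance gives 3.12%, or 547, in each direction on average. Transcripts are not independent and this count was not taken over other splits. How far it can vary by chance is therefore not known.

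Whole-count transcripts were tested alone with the embryo block, a fit picked after 17 fits had been seen. Of 6331 tested, 62 passed an adjusted p of 0.05 in edgeR, 14 higher and 48 lower with IWR-1. Without the block 2 passed, both lower. ENSGALT00000060409.1 was among the 62, at a log2 fold change of -0.98 (SE 0.07) and an adjusted p of 5.66e-05 that takes no account of the choice of fit. Most of the differences were small, with a median log2 fold change of -0.55 among the lower and 0.45 among the higher, and 11 exceeded 2-fold, 8 of them lower. The count depended on single embryos. It was 11 without embryo 77, 29 without 81, 38 without 76, 65 without 82 and 123 without 79. On the same whole-count transcripts with the block, limma-voom called 58 (15 higher, 43 lower), 54 of them among the 62, and DESeq2 called 145, with 61 of them among the 62. In fits over all transcripts, DESeq2 called 62 of the 62 with the block and 33 without it, and limma-voom with the block called 3. Over all transcripts edgeR called 0 of them with or without the block, and 1, ENSGALT00000060409.1, with the block and no robust shrinkage (adjusted p = 0.0447). With the block and a mean count of at least 500, edgeR called 18 of them.

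**Figure D2:**
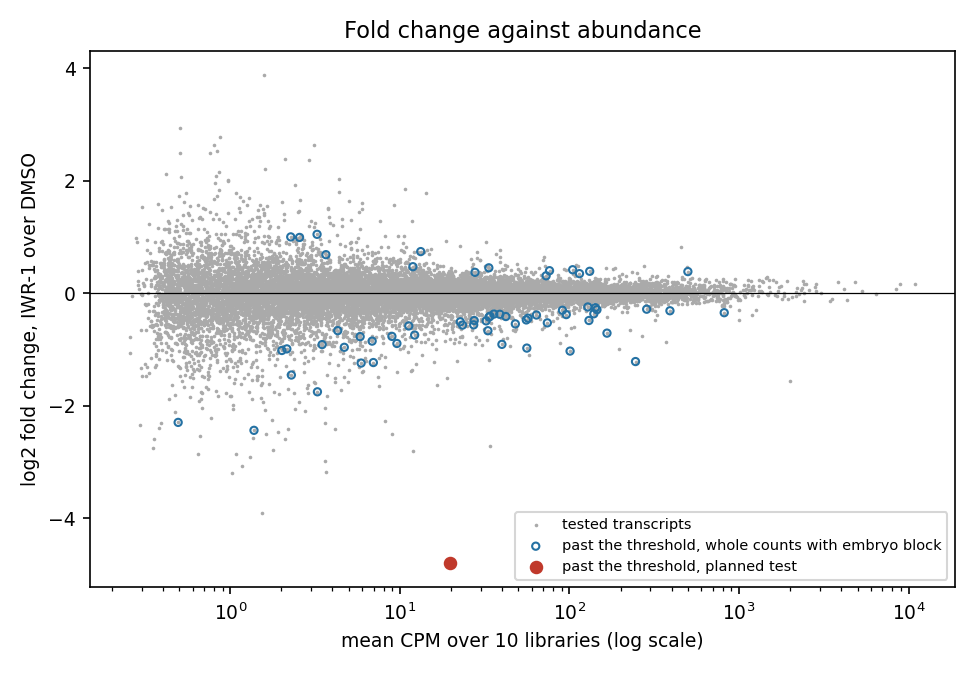
Log2 fold change, IWR-1 over DMSO (vertical axis), against mean CPM on a log scale (horizontal axis) for 17504 transcripts. The red point is ENSGALT00000040012.2, at -4.80, and blue rings are whole-count transcripts past the threshold with the embryo block.

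The added construct sequences were looked at in both groups. The NICD1 sequence had 41.4 ± 13.1 CPM with IWR-1 and 43.3 ± 12.04 CPM with DMSO (SD, n = 5), and the groups did not differ beyond their spread (two-sided exact permutation p = 0.81, adjusted p = 0.921). Within pairs the exact permutation p was 0.625 (adjusted p = 0.8125). The NICD1 counts carried decimals, so reads were divided with other sequences. They do not show that a construct was present. The sequences for mRFP, EGFP, mCherry, activated beta-catenin and the HA tags had 0 counts in all 10 libraries, which allows up to 3 counts per library. The Atoh1 construct sequence had 3 counts in 1 DMSO library and 0 in the others. These limits cover counting error only.

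The main axis of variation followed the embryo. Component 1 of the log2 CPM values held 16.7% of the variance and placed both otocysts of embryos 76 and 81 on one side and those of embryos 77, 79 and 82 on the other. Over 9 components, the smallest exact permutation p between IWR-1 and DMSO was 0.0952 (adjusted p = 0.657, two-sided). A single component that fully separated the groups would reach an adjusted p of 0.0714 at best, so this test could not have found it. Within pairs, all 5 embryos shifted the same way on component 4, which held 10.7% of the variance (exact permutation p = 0.0625, the smallest that 5 pairs allow, adjusted p = 0.375).

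**Figure D3:**
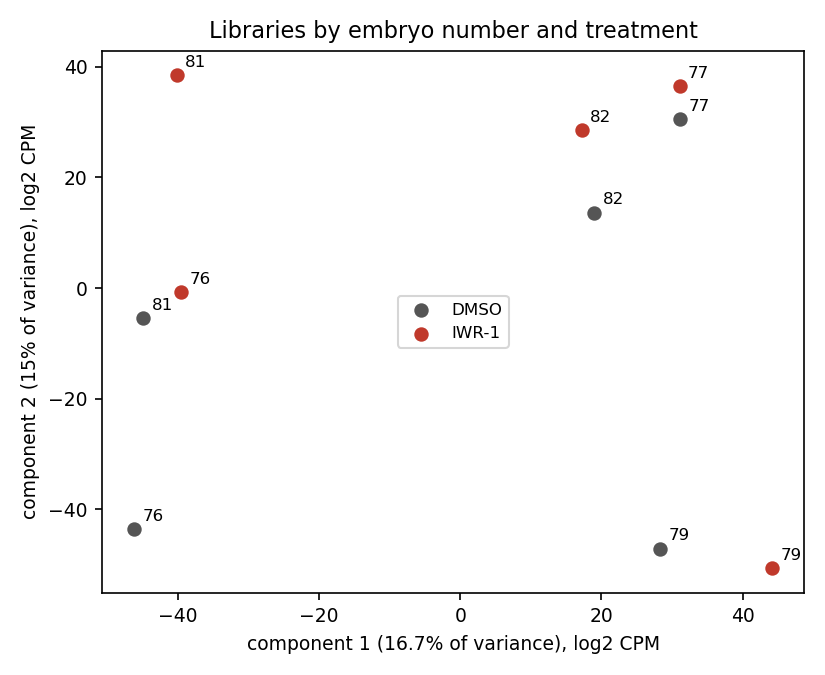
Component 1 (horizontal axis, 16.7% of variance) against component 2 (vertical axis, 15.0%) of log2 CPM for the 10 libraries, coloured by treatment and marked with the embryo number. Otocysts of embryos 76 and 81 have negative values on component 1.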

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

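Settings that go beyond the planned list, among them all those on whole-count transcripts, on abundance, and on robust shrinkage, were chosen after seeing the data. The 1 call was also found with RLE, upper-quartile and library-size scaling, without a filter, with at least 1 CPM in 5 libraries, with TPM at either pseudocount, without the 20 most abundant transcripts and at stricter thresholds. Limma-voom, with or without sample weights, gave 0. DESeq2 gave 134 (39 higher, 95 lower). With the replicate block edgeR gave 0, also with a length correction or on split-count transcripts alone, 3 without robust shrinkage, all lower, 8 with limma-voom (1 higher, 7 lower) and 614 with DESeq2 (252 higher, 362 lower). Whole-count transcripts without the block gave 2, or 3 without robust shrinkage, all lower. A mean count of at least 500 gave 3, all lower, and 51 with the block (18 higher, 33 lower). A mean count of at least 100 gave 8 with the block (1 higher, 7 lower). Leaving out 1 library or 1 embryo gave 0 to 2 calls, 0 to 1 higher and 0 to 2 lower. It was 0 without embryo 77, 79 or 81, without the IWR-1 library of 76, 77 or 79, and the 1 call without embryo 76 was a higher one. The cause of these differences was not tested apart from the tests on divided reads and on the number and abundance of transcripts. The fold of ENSGALT00000040012.2 kept its direction in the 40 alternatives that tested it, which leave out those on whole-count transcripts, at a log2 fold change of -5.08 to -3.69, with adjusted p from 5.07e-30 to 0.203. The other 3 named transcripts also kept their direction wherever they were tested.

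The 62 whole-count calls with the block became 2 without it (0 higher, 2 lower), 145 with DESeq2 (57 higher, 88 lower), 94 without a filter (24 higher), 10 at an adjusted p below 0.01, all lower, and 11 at 2-fold or more (3 higher, 8 lower). Adding merged read-sharing pairs gave 23 higher. Without 1 embryo the count was 11 to 123, with 0 to 52 higher and 11 to 71 lower. The cause was not tested. Transcripts whose groups did not overlap numbered 254 to 462 higher and 315 to 602 lower without 1 embryo, where 4 libraries against 4 give 250.1 by chance. The planned length offset, length-scaled TPM, GC correction and gene list tests were not run. Small changes could often be missed, since at these depths and with 5 libraries per group the planned test recovered 21.5% of simulated 1.5-fold changes. Depth and the number of changed transcripts were not varied in the simulations.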

Other observations

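Tests of divided reads, of the number and abundance of transcripts, of library scaling, of single embryos and of embryo labels were chosen after the result was seen. The predictions for the thinning test and for the counts over other splits were written before those values were seen. The thinning test and a count over splits used the whole-count fit, which was itself picked after the data were seen. Non-overlapping transcripts were also outside the planned list.

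The low number of calls over all transcripts may be related to reads divided among transcripts. At the same mean count, split-count transcripts had 1.91 times the residual variance of whole-count transcripts around the embryo-block fit (95% interval 1.8 to 2.11). The interval came from resampling transcripts, which are not independent, and does not cover variation between embryos. Testing fewer transcripts alone did not bring the count near the 62 of the whole-count fit. In 20 random sets of 6331 the median was 1 call and the highest 4. Abundance stays open. Split-count sets matched to the whole-count set on mean count gave at most 3 calls in 20 draws, but over all transcripts the block fit went from 0 calls to 51 at a mean count of at least 500. There it called 0.786% of split-count transcripts (33 of 4201) and 0.602% of whole-count transcripts (18 of 2990), with Fisher's exact p = 0.395, so split-count transcripts were not called less often there. Divided reads stay a candidate explanation, found and tested on the same data, and the abundant transcripts do not bear it out.

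Among the 62 whole-count calls, more were lower than higher with IWR-1. Library scaling and depth alone did not account for this. The lowest share of lower calls was 73.8% over 3 other scalings and was 73.9% after thinning all libraries to the smallest total. Without 1 embryo the share was 57.7% (79), 83.1% (82), 84.2% (76), 86.2% (81) and 100% (77). Without embryo 79 lower calls rose from 48 to 71 and higher calls from 14 to 52, so the smaller share does not show that the lower calls rest on that embryo. The body side, which goes with the treatment in every embryo, stays open and untested.

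More transcripts were absent from both otocysts of the same embryos under the labelled pairing than under any other. Most absences did not match between the otocysts. Of 1237 transcripts with at least 50 counts in some library and under 1 in another, 87 were absent from both otocysts of the same embryos, against 86 in the next best of 120 pairings and a median of 41. That margin is only 1, but 10 of 10 libraries also correlated best with the other otocyst of their own embryo, at 0.152 to 0.195 against at most 0.106 for other pairs, which argues against swapped embryo labels. The most frequent pattern was 24 transcripts absent from embryos 77, 79 and 82, the same embryos that component 1 set apart from 76 and 81. A difference in sex between embryos is a candidate explanation that cannot be told apart from others here, since the files do not pair IDs with names or chromosomes.

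Other splits of the 10 libraries bear on how far chance can be excluded. Of 100 splits into 5 against 5, 20 gave at least 1 call in the planned test, the highest other split 3, so chance cannot be excluded for the count of 1. For the 284 transcripts whose groups did not overlap, 8 of 126 splits gave as many, the highest other 494 in a split that kept both otocysts of embryos 76 and 79 together. Of the 7 other splits as large, 4 part 1 pair, and 3 keep the IWR-1 libraries of embryos 76, 77, 81 and 82 together with 1 DMSO library in place of that of embryo 79. This count over all splits ignores the pairing and does not exclude chance. The 16 splits that part all 5 pairs are too few for a share under 0.05. Among these, the whole-count fit with the block gave 62 calls for the real split and 0 for the highest other, 1 split being as large. That fit was picked after its calls on the real split were seen, and the choice was not repeated on the other splits. The contrast therefore leans towards the real split. DESeq2 with the block gave 614 and 640, with 2 splits as large, the 640 being the split that exchanges the otocysts of embryo 79. DESeq2 without the block gave 134 and 42, and non-overlapping transcripts 284 and 191, each with 1 split as large.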
